A study of Homo sapiens with 5 samples.

How the data were processed

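Total RNA of MCF-7 cells kept in culture medium with 10% serum was labelled with Cy3 and hybridized to Agilent 1-colour human arrays, with 2 arrays of cells given DMSO and 1 array each of cells given tamoxifen (1 µM), ganetespib (10 nM) or both, all for 10 days. Per the file headers, Agilent Feature Extraction 10.1.1.1 made the processed signal, an intensity from which local background was subtracted and spatial trends were removed within each array, with low spots replaced by a surrogate and no scaling between arrays. The submitters' notes name version 9.1. Per the file headers, the same program wrote a flag of 0 or 1 for spots well above background, a kind of value other than an intensity. The deposited table of values held log2 values for 42545 probes with near-equal distributions on all 5 arrays (medians 7.31 to 7.33), and its method was not stated. Its columns for DMSO replicates 1 and 2 matched each other's scanner file (Spearman's rho = 0.999993 and 0.999995) better than their own (rho = 0.992331 and 0.992338), so the scanner files set which array is which. Both belong to the same group, so the exchange changes no mean.

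Each array had 62976 spots, of which 4259 were controls and 58717 were used. Spots flagged as outliers by the scanner program were left out (268 to 502 per array), as were 55 probes with all spots so flagged on an array, and 0 spots were saturated. Well above background were 74.0% and 79.2% of spots with DMSO, 76.3% with ganetespib, 78.1% with tamoxifen and 84.4% with the combination, and the 75th percentiles of signal were 1895, 1923, 1541, 1778 and 2303. The 308 negative control spots per array had median signals from 2.80 (combination) to 4.79 (DMSO replicate 1). The number of arrays limits the precision of every value.

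The main values were log2 processed signals minus each array's 75th percentile over non-control probes. The log2 values of replicate spots were averaged per probe (999 probes had 10 spots and 7321 had 2), and a probe was well above background where at least 50% of its spots were. Of 42405 probes, 25422 were named through their accession, 1163 through a current symbol and 15820 by the name in the file alone. For 6244 genes with several probes, the probe with the highest mean over all 5 arrays stood for the gene. Of 34650 genes, 29632 were well above background on at least 1 array and were tested, and 24687 were so on all 5. Where one side of a comparison was not well above background, values on that side under the array's lowest signal well above background were raised to it, and the fold was printed as "at least". Probe positions in the files are on the human genome build hg19, for example 11 from 100900858 to 100900917 for PGR, 6 from 152423908 to 152423967 for ESR1, 6 from 29523477 to 29523536 for UBD and 10 from 91163438 to 91163497 for IFIT1. No annotation of exons or untranslated regions was at hand.

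Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend in the prior), with 1 coefficient per group, 1 residual degree of freedom and 5.85 prior degrees of freedom. Contrasts were each drug condition against the DMSO mean, the combination against each single drug, and the interaction. A lone drug array was assumed to vary like the DMSO arrays. Main effects came from a model without interaction (2 residual and 3.33 prior degrees of freedom). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, in two-sided tests. A rule without a test counted genes at least 2-fold from both DMSO arrays, or at least 2-fold between 2 single arrays. Correlations between responses were taken across genes, which are not independent replicates, and have no p. A reference for responses that share the DMSO arrays came from 100 simulations. The labels and file headers showed 1 slide and 1 scan day. DMSO replicate 1 lay in row 1 of the slide and the other 4 arrays in row 2, so no drug array could be compared within row 1.

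Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the 23 lists within each of 8 contrasts, and again with an estimated correlation, which was planned beside it and joined the alternatives after the data had been seen. Each list also had fry and a percentile of its median among 10000 random lists matched over 20 expression bins. The preset correlation called 110 list and contrast pairs and the estimated one called 0. The test with an estimated correlation rests on the residual degrees of freedom, 1 in the group model and 2 in the model without interaction. Almost no list could pass it with so few, so its 0 calls cannot decide for or against a list. The lists were estrogen-induced genes, estrogen-repressed genes, heat shock response, HSP90 co-chaperones and paralogs, HSP90 client transcripts, cholesterol synthesis, fatty acid synthesis, G1/S and DNA replication, G2/M and mitosis, unfolded protein response, integrated stress response, interferon response, p53 targets, hypoxia, NRF2 targets, AhR targets, glucocorticoid receptor targets and metallothioneins, lysosome and autophagy, immediate early and MAPK feedback, proteasome, luminal epithelial markers, basal and mesenchymal markers, and fibroblast markers. They held 460 distinct genes, of which 451 were measured. PCSK9, EPSTI1, AKR1C2, GBA, KRT5, COL1A2, COL6A3, PDGFRB and THY1 were not.

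The lists, comparisons, thresholds, alternatives and the rule for naming genes were fixed before the data were examined, except where an addition is named. The rule took genes with a symbol. For each drug condition against DMSO it took up to 10 higher and 10 lower genes with the largest changes among those that passed and were above background or gave a bound of at least 2-fold. For the other comparisons it took up to 5 each way, and for each list up to 4 members. It also took 12 genes in every comparison (ESR1, PGR, GREB1, TFF1, CCND1, MKI67, HSP90AA1, HSPA1A, HSPA8, DNAJB1, HSPH1 and BAG3). Genes named for uneven spots and the 5 gene families in the closing section were chosen after their values were seen.

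The tests were tested on simulated data with 50 genes changed at each size. Tamoxifen against DMSO recovered 38% of genes changed by 0.5 on the log2 scale, 72% at 1, 96% at 2 and 100% at 4, with 27 of 29432 unchanged genes called. Comparisons without simulated changes gave 0 calls among 29632 genes in limma. Of the list tests, 1 of 1 shifted lists and 0 of 100 unchanged lists were called. The 2-fold rule took 168 of 29432 unchanged genes. The simulated genes were drawn independently of each other, with the same spread on DMSO and drug arrays. These counts therefore do not show how the list tests behave where genes are correlated. Nor do they test the assumption that a lone drug array varies like the DMSO arrays. The simulated spreads were drawn from the prior with an intensity trend that limma had fitted to these data. The counts therefore cannot test that prior, on which the number of genes called depends. Changed genes were drawn only from those well above background on all arrays, so recovery among dimmer genes was not tested.

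Alternatives changed 1 choice at a time, except that normexp with quantile scaling and the deposited values changed background and scaling together. They were a normexp background (offset 50) with 75th percentile or quantile scaling, quantile normalization, scaling to the median of probes above background on all arrays, the deposited value table, 3 other filters on dim probes, a floor, the mean of all probes of a gene or every probe alone, eBayes without trend or with a robust prior, the spread of the model without interaction, adjusted p under 0.1, 1.5-fold in place of 2-fold, and each DMSO array left out. A limma treat test against 2-fold was added after the data had been seen. Other versions were Python 3.11.15 and matplotlib 3.10.9, and tables were read with the R package data.table (1.17.8).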

Results

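Gene expression was measured in MCF-7 cells, an estrogen receptor-positive human breast cancer line, after 10 days with the solvent DMSO, with tamoxifen at 1 µM, with ganetespib at 10 nM, or with both drugs together. Tamoxifen is an anti-estrogen that binds the estrogen receptor, and ganetespib (STA-9090) inhibits HSP90, a chaperone that steroid receptors and many kinases need for folding. The comparisons ask what each drug did alone, what the combination did, and whether the response to one drug differed in the presence of the other. DMSO had 2 arrays and each drug condition had 1, so no drug condition was replicated and the number of arrays limits the precision of every value. All 5 arrays lay on 1 slide and were scanned on 1 day. Between 74.0% of the spots (DMSO replicate 1) and 84.4% (combination) were well above background, so the combination array was the brightest.

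Across 24687 genes measured well above background on all 5 arrays, the 2 DMSO arrays correlated with r = 0.998 and their log2 difference had an SD of 0.19. Of the 29632 genes tested, 749 lay at least 2-fold apart between the 2 DMSO arrays. Each change is a log2 difference in normalized intensity from the mean of the 2 DMSO arrays, unless another reference is named, and each value after ± is its standard error from limma. The model took its spread from the DMSO pair and assumed that a lone drug array varied like the DMSO arrays. The p-values therefore measure only the spread between these samples, which may be technical, since the labels do not say whether the DMSO arrays came from separate cultures. Where a gene was not well above background on 1 side, a lower bound on the fold is given.

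Tamoxifen against DMSO asked what 10 days of anti-estrogen did to these cells. Estrogen-induced genes fell far, with the progesterone receptor gene PGR at -4.66 ± 0.08 (adjusted p = 5.94e-07) and the growth regulator GREB1 at -4.04 ± 0.12 (adjusted p = 2.28e-06). Most listed genes of DNA replication and all of those of mitosis fell, and the proliferation marker MKI67 fell by 0.73 on the log2 scale. Interferon response genes rose, among them IFIT1, which encodes an antiviral RNA-binding protein, by 4.81 ± 0.07. The estrogen receptor gene ESR1 fell by 0.64 ± 0.07 (adjusted p = 0.000454), and TFF1, a secreted trefoil protein induced by estrogen, fell by 2.90. CCND1, the cyclin D1 gene, was at -0.11 and did not pass the test (adjusted p = 0.233).

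Of 44 measured estrogen-induced genes, 31 fell and 6 rose with tamoxifen (31 and 6 adjusted over the list alone), with a median of -0.81 (adjusted p = 1.35e-11, and adjusted p = 0.477 with an estimated correlation). The kinase inhibitor gene PKIB fell by 4.31, while the keratin gene KRT13 rose by 4.05. Among 10 estrogen-repressed genes, 9 rose and 1 fell (9 and 1 adjusted over the list alone). The median was 1.52 (adjusted p = 4.9e-08, and adjusted p = 0.477 with an estimated correlation). They included PSCA, a surface antigen gene, at 4.36, the growth factor gene TGFB2 at 3.23, and BMF, a pro-apoptotic BCL2 family member, at 2.48. Cell cycle genes moved 1 way. Of the G1/S and DNA replication list, 28 of 33 genes fell (29 adjusted over the list alone). The median was -0.79 (adjusted p = 2.17e-16, and adjusted p = 0.477 with an estimated correlation). All 34 genes of the G2/M and mitosis list fell (34 adjusted over the list alone). The median was -1.14 (adjusted p = 2e-24, and adjusted p = 0.477 with an estimated correlation). Lower cell cycle genes included the kinetochore gene NUF2 at -1.45, the replication origin gene ORC1 at -1.42 and DHFR, which makes tetrahydrofolate, at -1.41.

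Interferon response genes rose in 27 of 28 measured members on the tamoxifen array (27 adjusted over the list alone), with a median of 2.17 (adjusted p = 1.6e-23, and adjusted p = 0.477 with an estimated correlation). XAF1 was at least 27.6-fold higher and RSAD2, the antiviral enzyme viperin, at least 30.5-fold higher, and the median was the same with such members entered at their bounds. HERC5, at -0.07, was the member that did not pass. Lysosome and autophagy genes rose in 13 of 21 and fell in 3 (14 and 3 adjusted over the list alone). The median was 0.28 (adjusted p = 0.000693, and adjusted p = 0.477 with an estimated correlation), led by GABARAPL1, an autophagosome protein gene, at 1.73. Of 7 targets of the aryl hydrocarbon receptor (AhR), 4 rose and 1 fell (5 and 1 adjusted over the list alone). The median was 0.81 (adjusted p = 0.0182, and adjusted p = 0.477 with an estimated correlation), with the xenobiotic-metabolizing enzyme gene CYP1A1 at 2.08 and the receptor's repressor AHRR at 3.25.

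Several metabolic and protein-handling lists fell with tamoxifen. Of 17 HSP90 co-chaperones and paralogs 12 fell (12 adjusted over the list alone). The median was -0.48 (adjusted p = 1.69e-05, and adjusted p = 0.477 with an estimated correlation), with the immunophilin genes FKBP5 at -1.15 and FKBP4 at -0.94. Proteasome genes fell in 22 of 31 (24 adjusted over the list alone). The median was -0.49 (adjusted p = 3.43e-09, and adjusted p = 0.555 with an estimated correlation), with PSMD14 at -0.93. Cholesterol synthesis genes fell in 14 of 24 and rose in 3 (15 and 4 adjusted over the list alone). The median was -0.35 (adjusted p = 0.00162, and adjusted p = 0.477 with an estimated correlation), with ACAT2 at -1.08. Fatty acid synthesis genes fell in 6 of 13 (6 adjusted over the list alone). The median was -0.16 (adjusted p = 0.0165, and adjusted p = 0.477 with an estimated correlation), with the desaturase gene FADS1 at -1.14. In the integrated stress response, the program that slows translation under stress, 11 of 20 genes fell and 3 rose (12 and 5 adjusted over the list alone). The median was -0.34, or -0.30 with bounds (adjusted p = 0.0174, and adjusted p = 0.477 with an estimated correlation). Lower members were the cystine transporter gene SLC7A11 at -1.81, the glutathione-degrading enzyme gene CHAC1 at -1.77 and the serine synthesis gene PHGDH at -1.64.

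The remaining lists did not pass with tamoxifen, and their counts are given as higher and lower members. Heat shock response had 6 and 11 of 26 (6 and 14 adjusted over the list alone, median -0.34, adjusted p = 0.0858), with HSPA1A, an inducible HSP70 gene, at 0.46 and HSP90AA1 at -0.06 (3 probes, -0.35 to -0.06). HSP90 client transcripts had 7 and 9 of 24 (7 and 9 adjusted over the list alone, median -0.07, adjusted p = 0.509), and the unfolded protein response 5 and 7 of 18 (5 and 9, median -0.21, adjusted p = 0.296). The p53 targets had 7 and 12 of 23 (9 and 12, median -0.24, adjusted p = 0.509), hypoxia 9 and 5 of 20 (9 and 6, median 0.14, adjusted p = 0.181) and NRF2 targets 5 and 6 of 15 (5 and 6, median -0.15, adjusted p = 0.586). Glucocorticoid receptor targets and metallothioneins had 3 and 6 of 12 (3 and 6, median -0.30, adjusted p = 0.236), and immediate early and MAPK feedback genes 12 and 6 of 20 (12 and 6, median 0.49, adjusted p = 0.0592), with the transcription factor EGR3 at -3.17 and JUN at 1.32. Of the marker lists, luminal epithelial markers had 7 and 2 of 19 (7 and 3, median 0.26, adjusted p = 0.117), basal and mesenchymal markers 4 and 4 of 14 (4 and 4, median 0.10, with a mean and test in the other direction, adjusted p = 0.822) and fibroblast markers 1 and 2 of 6 (2 and 2, median 0.86, or 0.27 with bounds, adjusted p = 0.952). In each pair of counts in brackets, the adjustment was over the list alone.

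The largest falls with tamoxifen were IGSF1 at -5.69 ± 0.08 (adjusted p = 2.42e-07) and MGP, the matrix Gla protein gene, at -5.14 ± 0.08 (adjusted p = 2.42e-07). Others that fell were the orphan receptor gene NR5A2 at -4.84, CHGA, the chromogranin A gene, at -4.72, and the neuropeptide Y receptor gene NPY1R at -4.53. The largest rises with all arrays above background were UBD, a ubiquitin-like modifier, at 5.12 ± 0.12 (adjusted p = 1.17e-06), ENTPD3 at 5.01 and DAB2, an endocytic adaptor, at 4.99 ± 0.10 (adjusted p = 7.45e-07). ADAMTS18 was at least 48.1-fold higher. SPANXN1 was at least 5013-fold higher, on a single spot whose pixels were more uneven than 99.8% of spots of like brightness.

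In all, 9960 of 29632 genes passed in tamoxifen, 5193 higher and 4767 lower (12252 had an unadjusted p under 0.05). By size alone, 2415 genes were at least 2-fold from both DMSO arrays, 1504 higher and 911 lower, against 749 between the DMSO arrays themselves. That count was 1213 with a convolution background (normexp), 1187 with normexp and quantile normalization and 1525 on the deposited values. Without an intensity trend in the prior, limma called 0 genes (9961 with an unadjusted p under 0.05), and with the spread of a model without interaction it called 830. Of the 20 genes with the largest changes, 15 passed with the latter spread and 0 without the trend.

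**Figure D1:**
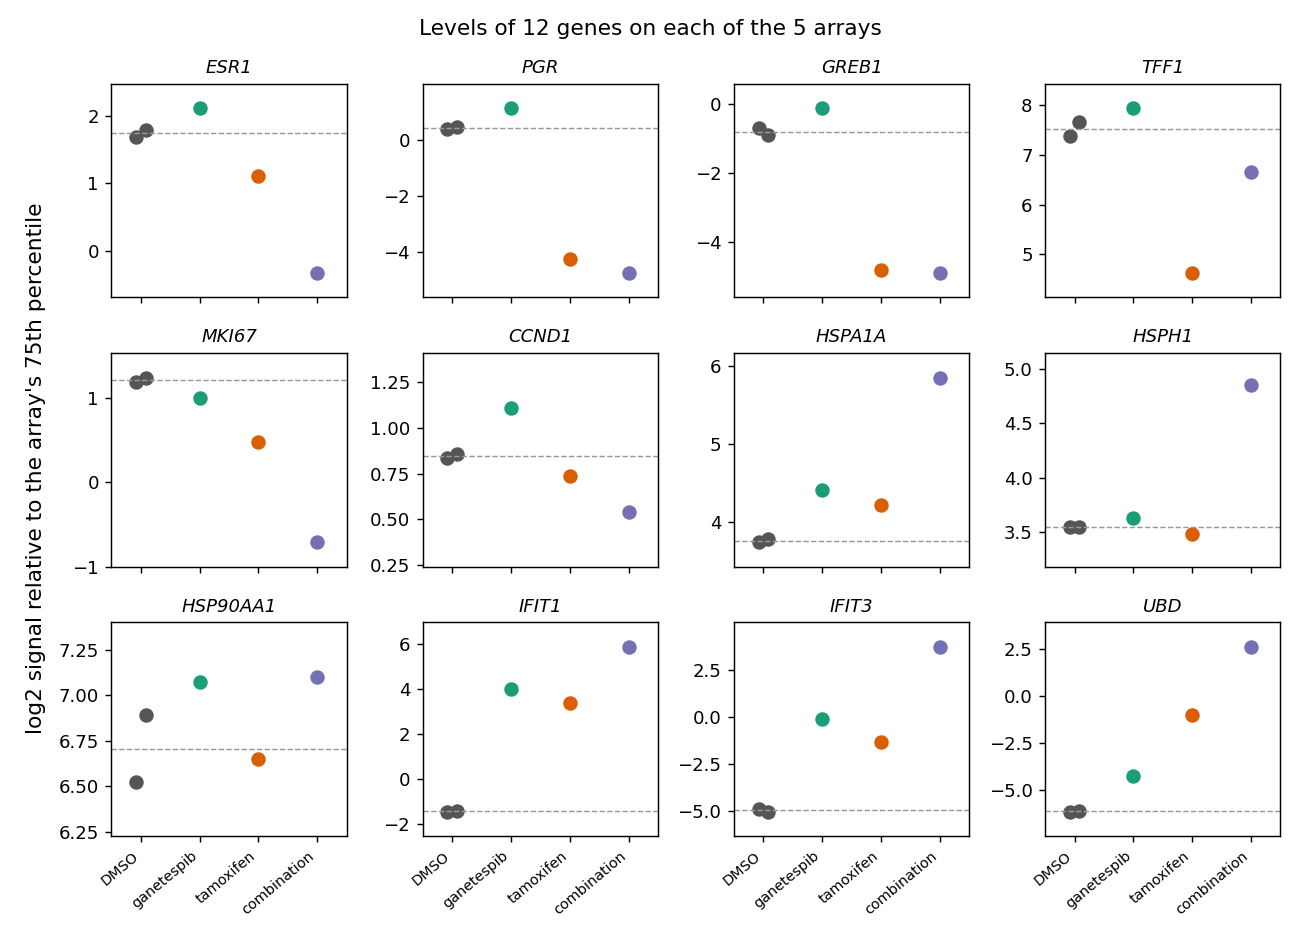
Levels of 12 genes on each of the 5 arrays, as log2 signal relative to the array's 75th percentile, with 1 point per array and a dashed line at the mean of the 2 DMSO arrays. ESR1 stood 0.64 below that line with tamoxifen and 2.06 below it with the combination, and IFIT1 stood above it on all 3 drug arrays.

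Ganetespib against DMSO asked what HSP90 inhibition alone did at 10 nM. Interferon response genes rose, with IFIT1 at 5.44 ± 0.07 (adjusted p = 2.28e-07), IFIT3 at 4.84 ± 0.09 and IFI27 at 4.60. ESR1 at 0.37 ± 0.07 (adjusted p = 0.00905), PGR at 0.71 and GREB1 at 0.68 rose, and TFF1 at 0.41 did not pass (adjusted p = 0.148). Of the chaperone genes, HSPA1A rose by 0.65 (adjusted p = 0.00251) and the HSP70 co-chaperone gene BAG3 by 0.93 (adjusted p = 0.000392). HSP90AA1 at 0.37 (3 probes, 0.11 to 0.37), DNAJB1 at 0.15 and HSPH1 at 0.08 did not pass, and the probes of HSPH1 disagreed in sign.

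All 28 measured interferon response genes rose with ganetespib (28 adjusted over the list alone), with a median of 2.94 (adjusted p = 4.36e-38, and adjusted p = 0.537 with an estimated correlation). XAF1 was at least 59.5-fold and RSAD2 at least 35.4-fold higher. Cholesterol synthesis genes rose in 18 of 24 (21 adjusted over the list alone). The median was 0.48 (adjusted p = 4.6e-11, and adjusted p = 0.537 with an estimated correlation), with MVD at 1.02 and LSS, the lanosterol synthase gene, at 0.86. Estrogen-induced genes rose in 21 of 44 and fell in 5 (21 and 7 adjusted over the list alone). The median was 0.29 (adjusted p = 0.000154, and adjusted p = 0.537 with an estimated correlation), with the hormone gene STC2 at 1.86 and the chemokine gene CXCL12 at 1.67. Estrogen-repressed genes rose as well, 8 of 10 with 1 lower (8 and 1 adjusted over the list alone). The median was 0.43 (adjusted p = 0.000196, and adjusted p = 0.537 with an estimated correlation), with PSCA at 1.56. Luminal epithelial markers rose in 6 of 19 and fell in 1 (9 and 1 adjusted over the list alone). The median was 0.34 (adjusted p = 0.000486, and adjusted p = 0.537 with an estimated correlation), with the mucin gene MUC1 at 1.79 and the androgen receptor gene AR at 1.16.

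Lysosome and autophagy genes rose in 12 of 21 (14 adjusted over the list alone). The median was 0.28 (adjusted p = 1.91e-06, and adjusted p = 0.537 with an estimated correlation), with the galactosidase gene GLA at 1.26. Glucocorticoid receptor targets and metallothioneins rose in 9 of 12 and fell in 1 (9 and 1 adjusted over the list alone). The median was 0.45 (adjusted p = 0.000144, and adjusted p = 0.537 with an estimated correlation), with the metal-binding MT1E at 1.03 and MT2A at 0.99. Hypoxia genes rose in 10 of 20 and fell in 2 (11 and 3 adjusted over the list alone). The median was 0.26 (adjusted p = 0.00153, and adjusted p = 0.537 with an estimated correlation), with ADM, the adrenomedullin gene, at 1.90.

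The cell cycle lists fell with ganetespib, by less than with tamoxifen in their medians. G2/M and mitosis genes fell in 20 of 34 (25 adjusted over the list alone). The median was -0.25 (adjusted p = 4.67e-11, and adjusted p = 0.537 with an estimated correlation), with CCNA2, the cyclin A2 gene, at -0.69. Genes of G1/S and DNA replication fell in 13 of 33 and rose in 1 (16 and 2 adjusted over the list alone). The median was -0.19 (adjusted p = 0.000154, and adjusted p = 0.537 with an estimated correlation). Proteasome genes fell in 14 of 31 (18 adjusted over the list alone). The median was -0.28 (adjusted p = 8.11e-07, and adjusted p = 0.537 with an estimated correlation). Co-chaperones and paralogs of HSP90 fell in 3 of 17 (3 adjusted over the list alone). The median was -0.17 (adjusted p = 0.0239, and adjusted p = 0.537 with an estimated correlation). Immediate early and MAPK feedback genes fell in 9 of 20 and rose in 3 (9 and 3 adjusted over the list alone). The median was -0.13 (adjusted p = 0.0428, and adjusted p = 0.537 with an estimated correlation). The last included the MAPK-induced genes DUSP6 at -1.53, ETV4 at -1.59 and ETV5, at least 9.30-fold lower.

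No call was made with ganetespib for the remaining lists, given as higher and lower members with the counts adjusted over the list alone in brackets. Heat shock response had 5 and 3 of 26 (5 and 4, median 0.05, adjusted p = 0.679), HSP90 client transcripts 7 and 6 of 24 (9 and 7, median 0.03, adjusted p = 0.635), and the unfolded protein response 5 and 3 of 18 (6 and 3, median -0.03, with a mean and test in the other direction, adjusted p = 0.712). The integrated stress response had 7 and 7 of 20 (7 and 8, median 0.01, with a mean and test in the other direction, adjusted p = 0.712): CHAC1 fell by 2.06 and SLC7A11 by 1.80, while the stress-induced regulator gene NUPR1 rose by 1.57. The p53 targets had 4 and 0 of 23 (4 and 0, median 0.07, adjusted p = 0.281), NRF2 targets 1 and 7 of 15 (1 and 7, median -0.14, adjusted p = 0.0549), AhR targets 3 and 0 of 7 (3 and 0, median 0.30, adjusted p = 0.162) and fatty acid synthesis 3 and 2 of 13 (3 and 3, median 0.04, adjusted p = 0.752). Basal and mesenchymal markers had 3 and 4 of 14 (3 and 6, median -0.38, adjusted p = 0.245) and fibroblast markers 1 and 1 of 6 (1 and 1, median -0.06, adjusted p = 0.957).

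Besides interferon genes, those that rose with ganetespib included KLK11, a secreted serine protease gene, at 5.26 ± 0.06 (adjusted p = 2.28e-07). Genes that fell included CRCT1 at -3.93, the keratin gene KRT6B at -3.87, the transglutaminase gene TGM2 at -3.40, the reductase gene AKR1B10 at -3.17 and S100A7, the psoriasin gene, at -3.08. FAM222A-AS1 at 9.87 ± 0.19 and DACT1, at least 909-fold higher, each rested on 1 spot whose pixels were more uneven than 99.6% and 99.8% of spots of like brightness.

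In all, 7001 genes passed with ganetespib, 3836 higher and 3165 lower (10128 had an unadjusted p under 0.05), and 1188 were at least 2-fold from both DMSO arrays, 797 higher and 391 lower. The latter count was 474 with normexp, 429 with normexp and quantile normalization and 591 on the deposited values. Without the trend limma called 0 genes (7435 with an unadjusted p under 0.05), with the spread of a model without interaction it called 11, and of the 20 genes with the largest changes 1 passed with that spread. With normexp 12423 genes passed, 73.0% of them higher against 54.8% here, while with scaling to common probes 44.5% were higher. Scaling to common probes shifts all genes alike and moved their median with ganetespib to -0.06. With normexp the list calls of estrogen-induced genes (median 0.28), hypoxia (median 0.27) and luminal markers (median 0.34) ended.

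The combination against DMSO asked what both drugs did together. Interferon response genes rose, with IFIT3 at 8.63 ± 0.09 (adjusted p = 3.01e-08), and so did UBD, which is not on that list, at 8.75 ± 0.12 (adjusted p = 5.1e-08). Estrogen-induced genes fell, with PGR at -5.14 ± 0.08 and GREB1 at -4.11 ± 0.12, and ESR1 itself fell by 2.06 ± 0.07 (adjusted p = 1.41e-06). MKI67 fell by 1.91 ± 0.06, and cell cycle lists fell in nearly all members. The chaperone genes HSPA1A at 2.10 ± 0.09 (adjusted p = 3.18e-06), HSPA6 at 2.45, HSPH1 at 1.31, DNAJB1 at 0.73 and BAG3 at 0.29 rose, while HSP90AA1 at 0.39 (adjusted p = 0.139) and HSPA8 at 0.04 did not pass, with other probes up to 1.12 for HSP90AA1 and at 0.88 for HSPA8.

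All 28 interferon response genes rose with the combination (28 adjusted over the list alone), with a median of 5.66 (adjusted p = 8.87e-26, and adjusted p = 0.499 with an estimated correlation). XAF1 was at least 828-fold, RSAD2 at least 459-fold and IFI44 at least 275-fold higher. Outside the list, the antiviral genes SAMD9L and TRIM22 were at least 228-fold and 225-fold higher, and the interferon lambda gene IFNL3 was at least 142-fold higher. Estrogen-induced genes fell in 34 of 44 and rose in 6 (34 and 6 adjusted over the list alone). The median was -0.99 (adjusted p = 1.52e-10, and adjusted p = 0.499 with an estimated correlation), with EGR3 at -6.02, the transcription factor gene MYB at -4.62 and AREG, a ligand of the EGF receptor, at -4.51. Estrogen-repressed genes rose in 9 of 10 (9 adjusted over the list alone). The median was 1.26 (adjusted p = 8.46e-07, and adjusted p = 0.499 with an estimated correlation), with PSCA at 4.90. Of the G1/S and DNA replication list 31 of 33 fell (31 adjusted over the list alone). The median was -1.30 (adjusted p = 1.61e-17, and adjusted p = 0.499 with an estimated correlation), with DHFR at -2.56 and CDC45 at -1.99. Again all 34 genes of the G2/M and mitosis list fell (34 adjusted over the list alone). The median was -1.38 (adjusted p = 2.68e-20, and adjusted p = 0.499 with an estimated correlation), with CCNA2 at -2.10.

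Of the stress lists, 2 rose with the combination, heat shock and integrated stress response, while the unfolded protein response and NRF2 targets did not pass. Heat shock response genes rose in 16 of 26 and fell in 3 (16 and 3 adjusted over the list alone). The median was 0.45 (adjusted p = 0.000265, and adjusted p = 0.499 with an estimated correlation). Integrated stress response genes rose in 11 of 20 and fell in 4 (12 and 4 adjusted over the list alone). The median was 0.39 (adjusted p = 0.00673, and adjusted p = 0.499 with an estimated correlation), with the stress-induced transcription factor genes ATF3 at 3.29 and DDIT3 at 3.06, where 3 of 4 probes of ATF3 had that sign. The p53 targets rose in 17 of 23 and fell in 3 (17 and 3 adjusted over the list alone). The median was 0.79 (adjusted p = 0.000178, and adjusted p = 0.499 with an estimated correlation), with GADD45A at 1.99. Hypoxia genes rose in 14 of 20 and fell in 1 (15 and 1 adjusted over the list alone). The median was 0.92 (adjusted p = 2.34e-06, and adjusted p = 0.499 with an estimated correlation), with NDRG1 at 4.28 and ADM at 4.04. Lysosome and autophagy genes rose in 14 of 21 and fell in 1 (14 and 1 adjusted over the list alone). The median was 0.55 (adjusted p = 2.09e-05, and adjusted p = 0.499 with an estimated correlation), with the autophagy receptor gene SQSTM1 at 1.82. Proteasome genes fell in 21 of 31 (22 adjusted over the list alone). The median was -0.45 (adjusted p = 1.08e-06, and adjusted p = 0.499 with an estimated correlation), with PSMB6 at -0.95 and PSMC3 at -0.88.

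Lists without a call in the combination follow as higher and lower members, with the counts adjusted over the list alone in brackets. HSP90 co-chaperones and paralogs had 3 and 7 of 17 (3 and 7, median -0.15, adjusted p = 0.23), HSP90 client transcripts 9 and 12 of 24 (9 and 12, median -0.28, adjusted p = 0.221), and the unfolded protein response 6 and 5 of 18 (6 and 5, median 0.03, adjusted p = 0.701), with the ER chaperone gene HSPA5 at 1.83. Cholesterol synthesis had 9 and 6 of 24 (10 and 7, median -0.04 with a mean in the other direction, adjusted p = 0.995) and fatty acid synthesis 3 and 7 of 13 (3 and 8, median -0.30, adjusted p = 0.204). NRF2 targets had 8 and 2 of 15 (8 and 3, median 0.31, adjusted p = 0.0955), with the heme oxygenase gene HMOX1 at 3.30, AhR targets 3 and 1 of 7 (3 and 1, median 0.39, adjusted p = 0.227), and glucocorticoid receptor targets and metallothioneins 4 and 3 of 12 (4 and 3, median 0.05, adjusted p = 0.77). Immediate early and MAPK feedback genes had 6 and 7 of 20 (9 and 7, median 0.24 with a mean in the other direction, adjusted p = 0.878) and luminal epithelial markers 6 and 6 of 19 (7 and 6, median -0.09, adjusted p = 0.878). Markers of other cells were basal and mesenchymal, 4 and 1 of 14 (4 and 1, median 0.26, adjusted p = 0.227), and fibroblast, 4 and 0 of 6 (4 and 0, median 1.44, adjusted p = 0.103).

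Among the genes that fell with the combination were MGP at -7.31 ± 0.08 (adjusted p = 3.01e-08), the keratin gene KRT6A at -6.89 ± 0.07 (adjusted p = 3.01e-08), IGSF1 at -6.12, ARHGAP36 at -5.87, KRT6C at -5.58, and the bone morphogenetic protein gene BMP5 at -5.27. The test called 13572 genes, 6968 higher and 6604 lower (15370 had an unadjusted p under 0.05). By size, 4830 genes were at least 2-fold from both DMSO arrays, 3319 higher and 1511 lower. Normexp left 2602 (57.2% higher against 68.7% here), normexp with quantile normalization 2529 and the deposited values 3079. Without the trend limma called 7353 genes and with the spread of a model without interaction 4168, and all 20 genes with the largest changes passed under either. On this brightest array, 81.4% of the 2-fold genes were higher among dimmer genes, 52.3% among brighter ones and 59.1% among those well above background on all 5 arrays.

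**Figure D2:**
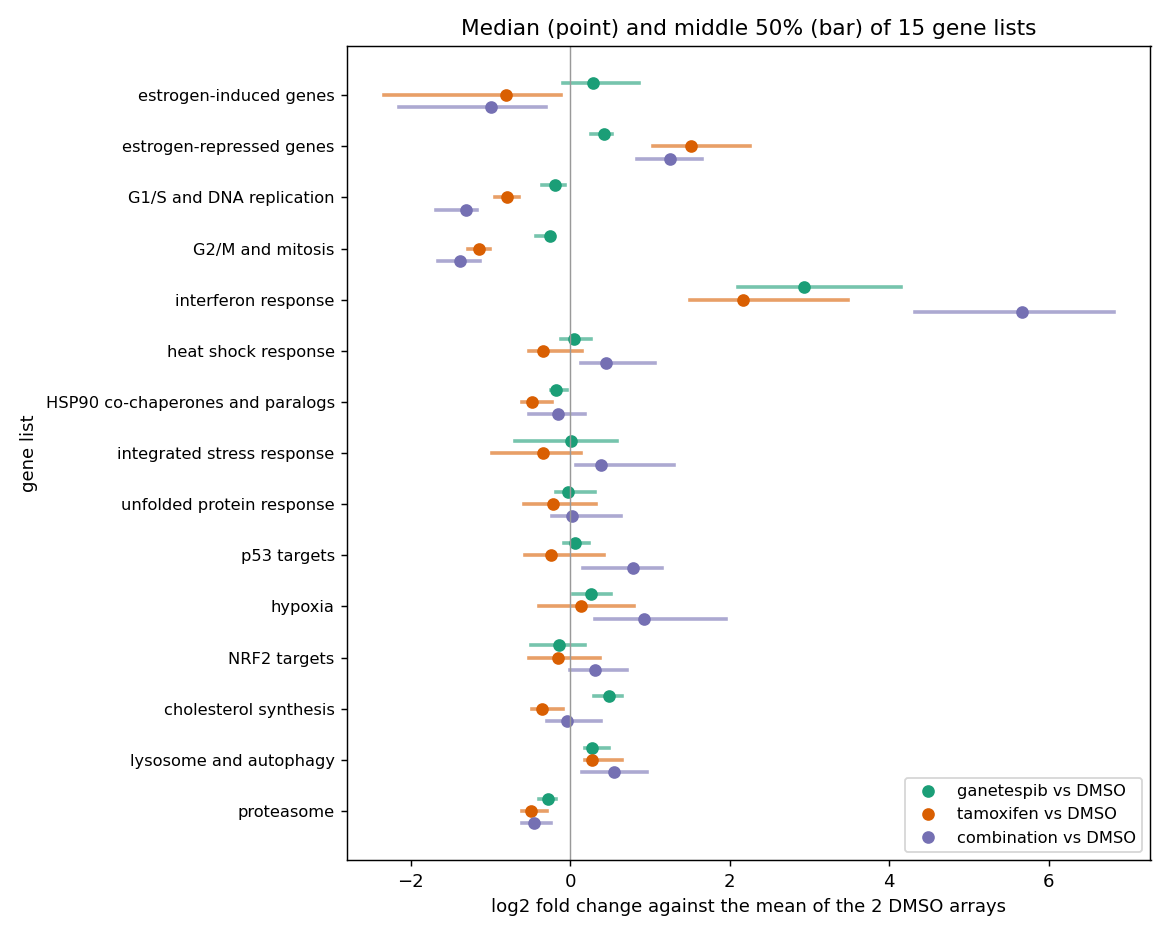
Median log2 fold change against DMSO (point) and middle 50% of members (bar) of 15 gene lists, with 1 colour per drug condition. The interferon response medians were 2.17 with tamoxifen, 2.94 with ganetespib and 5.66 with the combination, and the estrogen-induced medians were -0.81, 0.29 and -0.99.

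**Figure D3:**
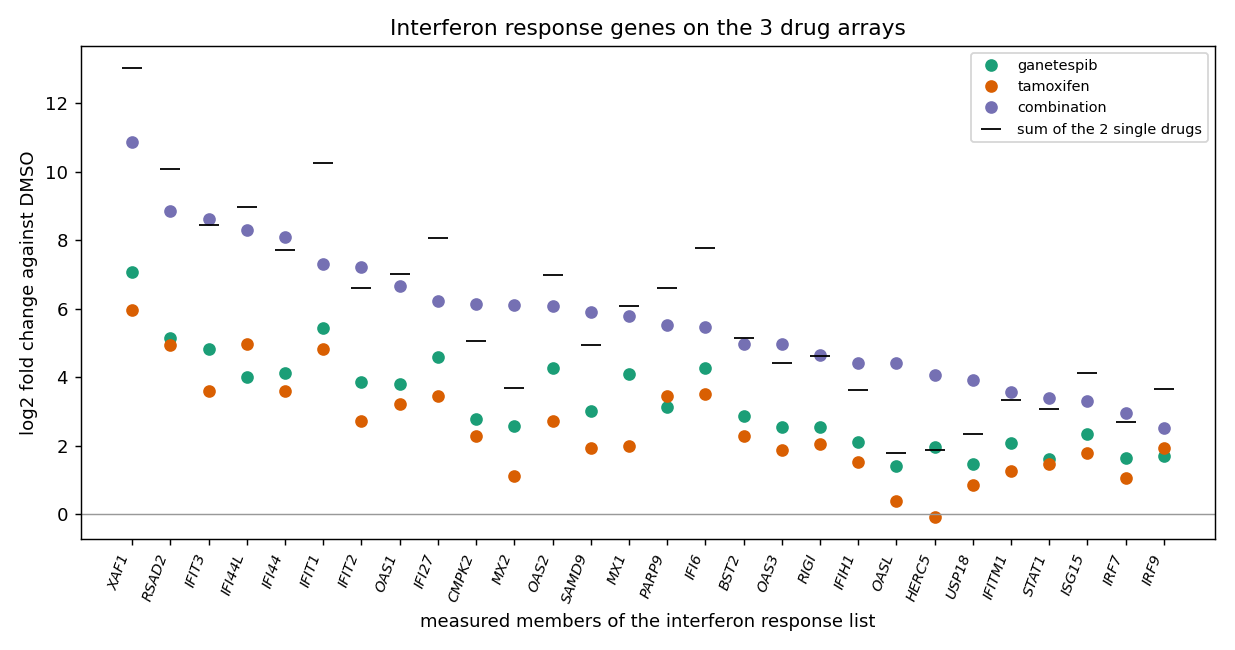
Log2 fold change against DMSO of the 28 measured interferon response genes on the 3 drug arrays, with a dash at the sum of both single-drug changes. XAF1, RSAD2 and IFI44 were not above background with DMSO, so their points are fitted values and not bounds, and IFIT1 lay 2.96 below its dash while OASL lay 2.61 above it.

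The combination against tamoxifen asked what ganetespib added to tamoxifen. Interferon response genes rose further, with IFIT3 at 5.03, and the interferon beta gene IFNB1 rose by 5.49 ± 0.24 (adjusted p = 2.07e-05). The chaperone genes HSPA1A at 1.63 ± 0.10 (adjusted p = 7.22e-05), HSPH1 at 1.38, HSPA8 at 0.53 and DNAJB1 at 0.40 rose, while HSP90AA1 at 0.45 and BAG3 at 0.15 did not pass. Other probes of HSP90AA1 reached 1.47 and the other probe of HSPA8 was at 1.95. ESR1 fell by 1.42 ± 0.08 (adjusted p = 5.08e-05) and MKI67 by 1.18, while TFF1 rose by 2.02 ± 0.20 (adjusted p = 0.000536). GREB1 was at -0.07 (adjusted p = 0.773), and its probes disagreed in sign.

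All 28 interferon genes rose against tamoxifen (28 adjusted over the list alone). The median was 3.21 (adjusted p = 3.58e-31, and adjusted p = 0.371 with an estimated correlation). Heat shock response genes rose in 20 of 26 (21 adjusted over the list alone). The median was 0.71 (adjusted p = 2.56e-11, and adjusted p = 0.371 with an estimated correlation), with DNAJB4 at 1.98. Co-chaperones and paralogs of HSP90 rose in 8 of 17 and fell in 2 (9 and 2 adjusted over the list alone). The median was 0.42 (adjusted p = 0.038, and adjusted p = 0.371 with an estimated correlation). The integrated stress response rose in 15 of 20 (15 adjusted over the list alone). The median was 1.002 (adjusted p = 2.56e-11, and adjusted p = 0.371 with an estimated correlation), with NUPR1 at 2.91, SLC7A11 at 2.23 and CHAC1 at 2.17. The p53 targets rose in 18 of 23 and fell in 1 (20 and 1 adjusted over the list alone). The median was 0.68 (adjusted p = 3.95e-09, and adjusted p = 0.371 with an estimated correlation). Hypoxia genes rose in 14 of 20 and fell in 1 (16 and 2 adjusted over the list alone). The median was 0.92 (adjusted p = 8.44e-08, and adjusted p = 0.371 with an estimated correlation), with NDRG1 at 3.11. The unfolded protein response rose in 9 of 18 (10 adjusted over the list alone). The median was 0.35 (adjusted p = 0.000433, and adjusted p = 0.371 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 24 and fell in 4 (13 and 4 adjusted over the list alone). The median was 0.34 (adjusted p = 0.00411, and adjusted p = 0.371 with an estimated correlation).

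G1/S and DNA replication genes fell further in 27 of 33 (29 adjusted over the list alone). The median was -0.52 (adjusted p = 1.19e-12, and adjusted p = 0.371 with an estimated correlation). G2/M and mitosis genes fell in 18 of 34 and rose in 6 (18 and 6 adjusted over the list alone). The median was -0.31 (adjusted p = 0.00138, and adjusted p = 0.371 with an estimated correlation). HSP90 client transcripts fell in 10 of 24 and rose in 3 (12 and 3 adjusted over the list alone). The median was -0.25 (adjusted p = 0.00616, and adjusted p = 0.371 with an estimated correlation). Fibroblast markers rose in 2 of 6 (2 adjusted over the list alone). The median was 0.91 (adjusted p = 0.0337, and adjusted p = 0.371 with an estimated correlation). In all, 18 of 23 lists passed, 12 upward and 6 downward, and 0 did with an estimated correlation (lowest adjusted p = 0.371). Estrogen-induced genes fell in 21 of 44 and rose in 13 (22 and 15 adjusted over the list alone). The median was -0.27 (adjusted p = 0.0337, and adjusted p = 0.47 with an estimated correlation), and the call ended with quantile normalization (median -0.27).

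Of single genes, SAMD9L was at least 163-fold and LST1 at least 56.9-fold higher than with tamoxifen alone, and TRIM22 was at 6.13. SPANXN1 was at least 8249-fold lower, the uneven spot of the tamoxifen array described above, and MFAP4, a matrix protein gene, at least 8.08-fold lower. The test called 8388 genes, 4047 higher and 4341 lower, and 3349 genes were at least 2-fold apart, 2539 higher and 810 lower. Of these size counts, normexp gave 1221 (62.5% higher against 75.8% here), normexp with quantile normalization 1234 and the deposited values 1591 (62.0%). Without the trend limma called 0 genes (8858 with an unadjusted p under 0.05), and with the spread of a model without interaction it called 10.

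The combination against ganetespib asked what tamoxifen added to ganetespib. PGR fell by 5.85 ± 0.10 (adjusted p = 3.35e-07), ESR1 fell by 2.43 ± 0.08 (adjusted p = 3.13e-06), and GREB1 was at -4.80 and TFF1 at -1.29. MKI67 fell by 1.71 with the cell cycle lists, UBD rose by 6.84 ± 0.14 (adjusted p = 6.06e-07), HSPA1A rose by 1.45 ± 0.10 (adjusted p = 5.66e-05) and HSPH1 by 1.23, while BAG3 was at -0.64 (adjusted p = 0.00148). KLK12, a kallikrein protease gene, fell by 6.74 ± 0.14 and MGP by 6.29 ± 0.09.

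Estrogen-induced genes fell in 35 of 44 and rose in 4 (38 and 4 adjusted over the list alone). The median was -1.41 (adjusted p = 1.22e-17, and adjusted p = 0.406 with an estimated correlation). Estrogen-repressed genes rose in 9 of 10 (9 adjusted over the list alone). The median was 1.04 (adjusted p = 2.8e-06, and adjusted p = 0.406 with an estimated correlation). G1/S and DNA replication genes fell in 30 of 33 and rose in 1 (30 and 1 adjusted over the list alone). The median was -1.13 (adjusted p = 3.71e-18, and adjusted p = 0.406 with an estimated correlation). G2/M and mitosis genes fell in 33 of 34 (33 adjusted over the list alone). The median was -1.04 (adjusted p = 1.32e-19, and adjusted p = 0.406 with an estimated correlation). All 28 interferon genes rose (28 adjusted over the list alone). The median was 2.35 (adjusted p = 3.81e-22, and adjusted p = 0.406 with an estimated correlation). Integrated stress response genes rose in 14 of 20 and fell in 2 (14 and 3 adjusted over the list alone). The median was 0.94 (adjusted p = 2.21e-05, and adjusted p = 0.406 with an estimated correlation). Of 23 p53 targets, 14 rose and 1 fell (14 and 1 adjusted over the list alone). The median was 0.61 (adjusted p = 7.5e-05, and adjusted p = 0.406 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 24 and rose in 2 (17 and 2 adjusted over the list alone). The median was -0.47 (adjusted p = 5.38e-06, and adjusted p = 0.406 with an estimated correlation). NRF2 targets rose in 9 of 15 and fell in 1 (9 and 1 adjusted over the list alone). The median was 0.50 (adjusted p = 0.000489, and adjusted p = 0.406 with an estimated correlation). Heat shock response genes rose in 14 of 26 and fell in 3 (15 and 3 adjusted over the list alone). The median was 0.41 (adjusted p = 0.000144, and adjusted p = 0.474 with an estimated correlation), with HSPA6 at 2.47.

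Among single genes, the axon guidance gene SEMA5B rose by 6.67 ± 0.16, and RASGRP3, a Ras activator, was at least 30.2-fold higher. FAM222A-AS1 at -9.02 and DACT1 at -8.65 were the uneven spots of the ganetespib array described above. The test called 10640 genes, 5175 higher and 5465 lower. Of the lists 16 passed, 9 upward and 7 downward, and 0 did with an estimated correlation (lowest adjusted p = 0.406). By size 4826 genes were at least 2-fold apart, 3366 higher and 1460 lower. This count was 2168 with normexp (49.5% higher against 69.8% here), 2121 with normexp and quantile normalization (55.2%) and 2680 on the deposited values (56.8%). Without the trend limma called 1946 genes and with the spread of a model without interaction 353. With normexp 17190 genes passed, 27.3% of them higher. Proteasome genes fell in 7 of 31 (6 adjusted over the list alone). The median was -0.19 (adjusted p = 0.0259, and adjusted p = 0.629 with an estimated correlation). With normexp, the list instead stood above other genes, at a median of -0.17. The call ended with quantile normalization (median -0.05), with 3 other treatments of dim genes (median -0.19) and on the deposited value table (median -0.03).

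The interaction asked whether the response to one drug differed in the presence of the other: a positive value means that the combination lay above the sum of both single-drug changes. Of the chaperone genes fixed beforehand, HSPH1 at 1.30 ± 0.12 (adjusted p = 0.000591), HSPA1A at 0.98 ± 0.13 and HSPA8 at 0.56 lay above that sum. BAG3 at -0.78 (adjusted p = 0.00396) lay below it, and DNAJB1 at 0.25 and HSP90AA1 at 0.08 did not pass. Other probes were higher, up to 1.36 for HSP90AA1 (3 probes) and 1.99 for HSPA8 (2 probes). Stress genes above the sum included CHAC1 at 4.23 ± 0.11, SLC7A11 at 4.03 and PHGDH at 2.65, all of which had fallen with each drug alone. Their log2 levels with the combination were near those with DMSO: 1.23 against 0.83 for CHAC1 and 0.22 against -0.20 for SLC7A11. For PHGDH the level was lower than with DMSO, 1.32 against 1.84. ESR1 lay below the sum at -1.79 ± 0.10, as did AR at -2.12, PGR at -1.19 and MKI67 at -0.98, while TFF1 lay above it at 1.61 ± 0.27. The kallikrein genes KLK12 at -7.40 and KLK11 at -5.98 ± 0.10 (adjusted p = 1.7e-06) had risen with ganetespib alone and not with the combination. KRT6B, at 5.38 ± 0.19 (adjusted p = 2.27e-05), had fallen with each drug alone by more than with both.

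Heat shock response genes lay above additivity in 21 of 26 and below it in 1 (22 and 1 adjusted over the list alone). The median was 0.80 (adjusted p = 1.37e-08, and adjusted p = 0.47 with an estimated correlation). Co-chaperones and paralogs of HSP90 lay above it in 8 of 17 (8 adjusted over the list alone). The median was 0.41 (adjusted p = 0.00196, and adjusted p = 0.47 with an estimated correlation). Integrated stress response genes lay above it in 15 of 20 and below it in 2 (15 and 2 adjusted over the list alone). The median was 0.98 (adjusted p = 7.49e-08, and adjusted p = 0.47 with an estimated correlation). The unfolded protein response lay above it in 9 of 18 and below it in 2 (10 and 2 adjusted over the list alone). The median was 0.43 (adjusted p = 0.00231, and adjusted p = 0.47 with an estimated correlation). The p53 targets lay above it in 14 of 23 and below it in 1 (16 and 2 adjusted over the list alone). The median was 0.55 (adjusted p = 2.39e-06, and adjusted p = 0.47 with an estimated correlation). Hypoxia genes lay above it in 9 of 20 and below it in 2 (11 and 2 adjusted over the list alone). The median was 0.45 (adjusted p = 8.44e-05, and adjusted p = 0.47 with an estimated correlation). NRF2 targets lay above it in 8 of 15 (10 adjusted over the list alone). The median was 0.65 (adjusted p = 0.000162, and adjusted p = 0.47 with an estimated correlation). Below additivity were 24 of 44 estrogen-induced genes with 7 above (27 and 7 adjusted over the list alone). The median was -0.58 (adjusted p = 7.52e-06, and adjusted p = 0.47 with an estimated correlation). Also below were 6 of 10 estrogen-repressed genes with 1 above (8 and 1 adjusted over the list alone). The median was -0.54 (adjusted p = 0.000537, and adjusted p = 0.47 with an estimated correlation). So were 15 of 33 G1/S and DNA replication genes with 2 above (18 and 2 adjusted over the list alone). The median was -0.31 (adjusted p = 2.21e-05, and adjusted p = 0.47 with an estimated correlation). Luminal epithelial markers lay below in 8 of 19 (14 with 1 above adjusted over the list alone). The median was -0.58 (adjusted p = 3.42e-05, and adjusted p = 0.47 with an estimated correlation), with MUC1 at -1.99.

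The interferon list did not pass the interaction test (9 above and 9 below of 28, and 10 and 11 adjusted over the list alone; median 0.11 with a mean in the other direction, adjusted p = 0.912). OASL at 2.61 and MX2, a GTPase that blocks viruses, at 2.43 lay above additivity, and IFIT1 at -2.96 and IFI6 at -2.31 below it. The list passed upward with normexp (median 0.50), with normexp and quantile normalization (0.61) and on the deposited value table (0.51). G2/M and mitosis genes did not pass either (10 above and 7 below of 34, and 13 and 9 adjusted over the list alone; median 0.10, adjusted p = 0.631). In all, 7205 genes passed, 3280 above and 3925 below, and 16 lists, 9 above and 7 below, of which 0 passed with an estimated correlation (lowest adjusted p = 0.47). Without the trend limma called 0 genes (7933 with an unadjusted p under 0.05), and with normexp it called 12241, 27.6% of them above.

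Across all 29632 genes, which are not independent replicates, the tamoxifen response without ganetespib correlated with that in its presence at r = 0.442 (Spearman's rho = 0.346). The ganetespib response without tamoxifen correlated with that in its presence at r = 0.162 (rho = 0.0794). For genes at least 2-fold changed by the single drug the values were r = 0.686 over 2415 genes, 82.9% with the same sign, and r = 0.301 over 1188 genes, 61.7% with the same sign. For any gene, the response with the other drug differs from that without it by the same interaction value for both drugs. Across all genes the tamoxifen response against DMSO varied more (SD 0.71) than the ganetespib response (SD 0.56). The correlations therefore do not show which response the other drug altered more. Of 5193 genes higher with tamoxifen, 2628 were also higher in the combination against ganetespib, where independence would give 907, and 570 were lower. Of 3836 genes higher with ganetespib, 1236 were also higher in the combination against tamoxifen, where independence would give 524, and 780 were lower. In these overlaps both comparisons used the same spread for a gene, so genes with a small spread tend to pass in both, in the same or the opposite direction. Independence is therefore too low a reference, and an overlap above it is no sign by itself of a shared response. The tamoxifen and ganetespib responses, which share the DMSO arrays, correlated at r = 0.461, where simulations without any drug response gave 0.333. With a separate DMSO array for each drug, the measured correlation was r = 0.343 and the simulated one was 0.000167.

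**Figure D4:**
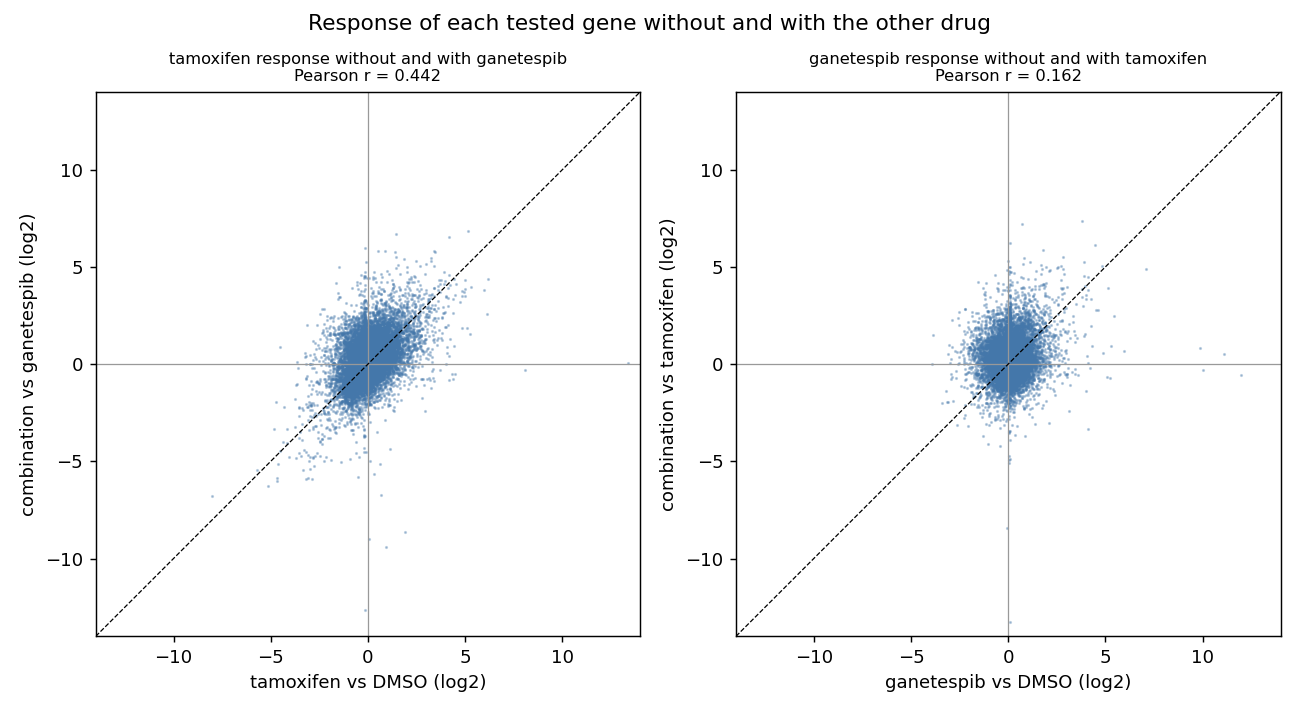
Log2 response of each tested gene to tamoxifen (left) and ganetespib (right), without the other drug on the horizontal axis and with it on the vertical axis, with a dashed line of equal response. The responses without and with the other drug correlated at r = 0.442 for tamoxifen and r = 0.162 for ganetespib. The vertical distance of a gene from the line is its interaction value and is the same in both panels.

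The main effects, from a model without interaction, asked which changes a drug brought both with and without the other. For tamoxifen, MGP at -5.63 ± 0.27 (adjusted p = 0.00231), IGSF1 at -5.58 ± 0.13, PGR at -5.17 ± 0.28 and GREB1 at -4.37 ± 0.21 fell. Rises were UBD at 5.86 ± 0.39, DAB2 at 4.50, VGLL1 at 4.41 and the lipocalin gene APOD at 4.36. ESR1 at -1.41 did not pass (adjusted p = 0.0944). For ganetespib, IFIT3 at 4.92 ± 0.13 (adjusted p = 0.00282), IFIT2 at 4.15, MX1 at 3.96 and OAS2 at 3.88 rose, all genes of the interferon response. The cornified envelope gene SPRR1B at -2.85, S100A7 at -2.61 and KRT6A at -2.54 fell. None of the 12 genes fixed beforehand, ESR1, PGR, TFF1 and the chaperone genes among them, passed for ganetespib. Interferon response genes rose with tamoxifen in 24 of 28 (27 adjusted over the list alone). The median was 2.27 (adjusted p = 6.98e-24, and adjusted p = 0.084 with an estimated correlation). With ganetespib they rose in 21 of 28 (28 adjusted over the list alone). The median was 3.25 (adjusted p = 7.99e-45, and adjusted p = 0.0882 with an estimated correlation). G2/M and mitosis genes fell with tamoxifen in 30 of 34 (34 adjusted over the list alone). The median was -1.11 (adjusted p = 8.01e-25, and adjusted p = 0.084 with an estimated correlation). For ganetespib, 12 of 24 cholesterol synthesis genes rose adjusted over the list alone and 0 over all genes (median 0.44, adjusted p = 1.39e-08, and adjusted p = 0.264 with an estimated correlation). In all 2926 genes passed for tamoxifen, 1622 higher and 1304 lower. For ganetespib 141 passed, 117 higher and 24 lower (4215 had an unadjusted p under 0.05), against 32 to 232 with other scalings. Left without DMSO replicate 1 or replicate 2, the fit called 740 to 827 genes for tamoxifen and 34 to 37 for ganetespib. Without the trend it called 951 and 0 (3693 with an unadjusted p under 0.05 for ganetespib).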

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

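The test of place on the slide for the interferon genes and that of unevenness for probe A_33_P3288919 were chosen only after the result was seen.

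The response to one drug differed in the presence of the other by limma's interaction test for 7205 genes and 16 gene lists, although 0 genes passed without the intensity trend (7933 at an unadjusted p under 0.05) and 0 lists with an estimated correlation (lowest adjusted p = 0.47). Named genes above the sum of both single-drug changes, by this test, were KRT6B at 5.38, a keratin gene whose paralogs KRT6A and KRT6C are close in sequence. SEMA5B was at 5.25 in the same test. CCL26, a chemokine gene, was at 4.42. CHAC1, which degrades glutathione, was at 4.23, after a fall with each drug alone. PLAC8 was at 4.21. Below the sum were FAM222A-AS1 at -9.04, on the uneven spot weighed further on, and KLK12 at -7.40. KLK11 was at -5.98. CXCL14, another chemokine gene, was at -5.10. UGT2B15, which attaches glucuronic acid to steroids, was at -3.99.

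Interferon response genes were higher on all 3 drug arrays, with medians of 2.17, 2.94 and 5.66. Scaling alone does not account for this, since the lowest of 15 medians over 5 other scalings was 1.87. Immune cell RNA mixed in would need its own markers to rise as well, but the 16 measured of 17 fixed markers had a median of 0.082 with the combination (spread 0.629), with PTPRC at -0.004, CD14 at 1.21 and CORO1A at -1.40. Place on the slide and drug condition cannot be told apart, since each array of the drug arrays' row had its own column, although DMSO replicate 2, in that row, was at -0.00336 (spread between members 0.263) against replicate 1. A response of the cells to the drugs and a difference between cultures, with 1 array per drug condition, were not tested and stay open.

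More genes were at least 2-fold higher than lower on the combination array, 3319 against 1511. Among genes brighter than the median gene 52.3% of 2105 were higher (exact Clopper-Pearson 95% interval 50.1% to 54.5%), against 81.4% among the dimmer ones, so dim probes on the brightest array are a candidate explanation for part of the excess, although 59.1% of the 3330 genes well above background on all 5 arrays were higher too. With quantile normalization 59.4% of 4572 were higher (58.0% to 60.8%), between the values set in advance for and against scaling as the cause, so scaling and a true excess cannot be told apart. Both intervals count genes as independent, which they are not, and hold no spread between arrays or cultures. A drug response of weakly expressed genes was not tested and stays open.

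Of the genes tested, 6 stood at least 6 log2 units higher on 1 array than on the other 4, 4 on the ganetespib array, 2 on the tamoxifen array and 0 on the others. The pixels of their spots were more uneven than a median of 99.6% of 1000 spots of like brightness (5 of 6 at or above 95%), against a median of 45.6% and 0 of 28 for interferon genes on the combination array, so an uneven or damaged spot may account for SPANXN1, DACT1, FAM222A-AS1 and 2 long noncoding RNA probes. The spot of A_33_P3288919, which has no gene symbol in the files, was at 35.8%, which argues against unevenness as the reason for its signal with ganetespib. Whether the signal belonged to the probe or to the gene cannot be told apart, since 0 of 0 genes with another probe could be compared. No biological explanation was tested.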

How the results depend on the processing

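The treat test, and the estimated correlation as an alternative, were chosen only after the result was seen, and all other alternatives were planned. Of 15988 tested values of 1073 named results, 14432 kept their direction and their side of the threshold, 48 uncalled ones changed sign, 1310 lost the call, 186 gained one and 12 reversed. Without the trend 629 of 1073 lost the call, and with the spread of the model without interaction 453 of 709. Changes to the filter, the prior or the threshold alone leave a fold change as it was, so a kept direction there is no test. The same holds for every probe alone, which kept the main probe of each named gene. Another 1744 values, from leaving out a DMSO array, had no test, and 1731 of them kept their direction. List tests at the preset correlation kept direction and side in 1915 of 2116 values, with 71 uncalled sign changes, 67 calls lost, 62 gained and 1 reversed, while the estimated correlation took the 110 list calls to 0. With 1 or 2 residual degrees of freedom almost no list could pass with an estimated correlation, so that loss cannot decide for or against a list. For each value below the cause was not tested, unless a reason is given.

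Without the intensity trend, limma called 0 genes with tamoxifen (9961 at an unadjusted p under 0.05), 0 with ganetespib (7435), 0 in the combination against tamoxifen (8858), 0 for the interaction (7933) and 0 for the ganetespib main effect (3693). It called 7353 in the combination, 1946 against ganetespib (61.0% higher, 48.6% before) and 951 for the tamoxifen main effect. With the spread of the model without interaction, which counts any interaction as noise, 830 passed with tamoxifen, 11 with ganetespib (100% higher), 4168 with the combination, 10 against tamoxifen (100% higher) and 353 against ganetespib (64.0% higher). The treat test against 2-fold, which asks for larger changes by construction, called 801, 237 and 2132 in the drug conditions, 559 against tamoxifen, 1309 against ganetespib, 443 for the interaction, and 148 and 13 for the tamoxifen and ganetespib main effects. At adjusted p under 0.1, a looser threshold, the main effects had 4946 and 475.

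Normexp with the 75th percentile gave 12423 genes with ganetespib (73.0% higher, 54.8% before), 17190 against ganetespib (27.3%, 48.6% before), 12241 for the interaction (27.6%, 45.5% before) and 232 for the ganetespib main effect. It moved the median of all genes to 0.15 with ganetespib, -0.10 against tamoxifen, -0.23 against ganetespib and -0.24 for the interaction, and for ganetespib, against ganetespib and the interaction the shift had the sign of the excess of calls. Quantile normalization moved the combination median to -0.10 and gave 80 genes for the ganetespib main effect, normexp with quantile 32, and the deposited values 58. Scaling to common probes, which shifts all genes alike, moved the ganetespib median to -0.06 and made 44.5% of genes called with ganetespib higher.

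By the 2-fold rule (2415, 1188, 4830, 3349 and 4826 in the report), normexp left 1213 with tamoxifen, 474 with ganetespib, 2602 with the combination (57.2% higher, 68.7% before), 1221 against tamoxifen (62.5%, 75.8% before) and 2168 against ganetespib (49.5%, 69.8% before). In the same order, normexp with quantile left 1187, 429, 2529 (57.9%), 1234 (61.8%) and 2121 (55.2%), and the deposited values 1525, 591, 3079, 1591 (62.0%) and 2680 (56.8%). Quantile alone moved the share higher to 62.1% against tamoxifen and 59.6% against ganetespib. Genes above background on all 5 arrays, fewer by construction, left 753 with ganetespib, 1803 (64.2%) against tamoxifen and 2910 (56.0%) against ganetespib, and on all arrays compared 771, 2085 and 3188 (57.1%). At 1.5-fold, a looser rule, the counts were 5575, 3287, 9299, 7626 and 9802.

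The correlation of tamoxifen responses was 0.524 with normexp, 0.536 with normexp and quantile, 0.525 on the deposited table, 0.524 (0.5235) for genes above background on all arrays, 0.507 on at least 2, 0.414 without filter and 0.497 with a floor. For ganetespib it was 0.200 (0.2003), 0.212, 0.210 and 0.1995 in the first 4.

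Without DMSO replicate 1 or replicate 2, the tamoxifen main effect called 740 to 827 genes (740 without replicate 2), the ganetespib main effect 34 to 37, and the correlations were 0.413 to 0.442 for tamoxifen and 0.131 to 0.175 for ganetespib. The group model has no residual degree of freedom without either array, so its counts have no such value.

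Reversed with normexp were COL3A1 (-0.19) and TP63 (-0.22) against ganetespib, IFI16 with ganetespib (0.36), KRT6C (0.43) and PSAT1 (-0.10) in the interaction, and the proteasome list against ganetespib (median -0.17, above other genes). KRT6C also reversed with normexp and quantile (0.71) and on the deposited table (0.52), where GREB1 against tamoxifen was at 0.51. With the mean of all probes, which brings in probes that disagreed, PSMA1 with the combination (0.26), GREB1 against tamoxifen (1.12) and in the interaction (0.26) and SPRR2D with ganetespib (-0.74) reversed. Signal over background limits part of the data, since 4945 of 29632 genes were not well above background on all 5 arrays. No paired analysis was possible because each drug condition had 1 array.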

Other observations

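The 5 gene families here were chosen only after their values were seen, and no test of a cause was run on them.

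Of 14 measured antigen presentation genes, 10 were higher with tamoxifen, 8 with ganetespib and 14 with the combination, and 11 lay above the sum of both single-drug changes, while HLA-F with tamoxifen, which did not pass, changed sign with scaling to common probes. With the combination, the class I light chain gene B2M was at 2.29, HLA-B at 2.07, the peptide transporter gene TAP1 at 3.97 and the immunoproteasome gene PSMB9 at 5.60. Genes of interferons, chemokines and the death ligand TNFSF10 were higher in 7 of 11 with each single drug and in 11 of 11 with the combination, where CXCL9 and CXCL11 with tamoxifen, which did not pass, changed sign between scalings and the call of CXCL10 was lost under some. The interferon lambda genes IFNL1 and IFNL2 were at 6.13 and 5.50 with the combination and the chemokine gene CCL5 at 5.72. Among 11 sensors of foreign nucleic acid and their signalling adaptors, 2 of them members of the interferon list, 8 were higher and 2 lower with the combination. The 2 lower ones were the adaptor genes MAVS at -0.51 and STING1 at -0.40, while the adaptor gene TICAM1 was higher at 1.28. With the combination the RNA sensors RIGI, IFIH1 and DHX58 were at 4.66, 4.43 and 4.51. The DNA sensor gene CGAS was at -0.91 with tamoxifen and at 0.16 with the combination, where it did not pass. It lay above the sum of both single-drug changes at 1.65. IFI16 was well above background on 1 array, so its 4.18 with the combination is a fitted value and not a bound. With ganetespib IFI16 did not pass and changed sign with normexp.

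Of 18 chosen genes of squamous epithelium and its cornified envelope, 15 fell with tamoxifen, 16 with ganetespib and 14 with the combination, and 0 passed as higher by limma; SPRR2D with ganetespib, TGM1 with the combination and KRT6C in the interaction, which did not pass, changed sign under other settings. With the combination KRT6A was at -6.89, SPRR1B at -5.23 and S100A7 at -5.15, and 12 of the 18 lay above the sum of both single-drug changes and 2 below it. Of 10 measured kallikrein protease genes, 5 were higher and 1 lower with ganetespib, and 2 higher and 5 lower with the combination, and 6 lay below the sum of the single-drug changes. KLK11 was at 5.26 with ganetespib and -0.39 with the combination, and KLK12 at 4.09 and -2.66. KLK10 with the combination, KLK9 with ganetespib and in the interaction, and KLK7 and KLK14 in the interaction, which did not pass, changed sign between scalings.

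Of 785 probes with 10 spots each, 26.8% differed between the DMSO arrays by more than 2 standard errors of their spots, where spot noise alone would give 6.08%. Of the 749 genes at least 2-fold apart between those arrays, 290 were higher in replicate 1 and 459 in replicate 2, and 41 were well above background on all 5 arrays.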
